A study of Mus musculus with 9 samples.

How the data were processed

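ATAC-seq libraries of sorted P14 CD8 T cells from tumor-draining lymph nodes were compared between days 4, 8 and 21 after transfer, with 3 libraries per day. Groups and replicate numbers were taken from the sample titles, because the tags for genotype and time point carry each other's values. The labels do not say whether the 3 libraries of a day came from separate animals.

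Per the submitters' processing notes, BWA 0.7.15, Picard, MACS2 and deepTools 2.0 were used with mm10, in roles the notes do not give. Read filters, the treatment of reads with several matching places, any shift of reads for Tn5 and the MACS2 settings are not given in the sources used here. The deposited values were 9 narrowPeak lists, 1 per library, so the authors called peaks per sample. Each deposited list gives a peak's position, a score, a fold enrichment at the summit over the library's own local background, and −log10 of its p and q values, as the authors' peak caller wrote them. These values were used only to describe, rank or filter peaks within a list and to recover depth. All peaks had a q of 0.05 or less.

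Peaks on chromosomes 1 to 19 and X were kept, 353507 over the 9 lists. All lists were merged into 62963 union regions wherever peaks shared at least 1 base, and a region counted as called in a list that had a peak sharing at least 1 base with it. A region was gained when called in 3 of 3 lists of the later day and 0 of 3 of the earlier day, and lost in the reverse case. Coordinates are 1-based on mm10.

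Read totals are not in the lists. The fold enrichment and −log10 p of a peak together fix a whole-number summit pileup and a local background, under the Poisson formula of MACS2. A whole pileup was recovered for 100% of 5000 simulated peaks and for at least 99.995% of the peaks of every real list (tolerance 0.001 in −log10 p), and the smallest background of a list stands for its depth. Pileups were compared only to describe depth and to set same-day lists against sampling noise. A summit is a maximum, and in 9 simulated settings with assumed peak profiles its variance was 0.548 to 0.993 of its mean, so a chi-square per region below 1 partly follows from taking a maximum.

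Gene positions came from the 21631 protein-coding genes of a RefSeq table for GRCm38.p6, the assembly of mm10, which gives no strand and no transcripts. The planned distance to a transcription start was therefore replaced by the distance to the nearer end of a gene, and the planned promoter share became the share of peaks within 1 kb of either gene end. A locus holds the regions that overlap a gene body and other regions nearest to the gene's boundary within 100 kb. This placed 95.3% of regions, and 3.06% of all regions lay in several genes. No genome was used here, so the planned motif analysis was not run. Of 347 gene symbols fixed in 16 lists before the data were examined, 344 matched, and the 3 others are not analysed here.

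For each gene with at least 3 union regions, log2((regions called + 0.5) / (regions called in the list relative to the mean over lists)) was fitted with limma 3.58.1 (trend, robust) in R 4.3.3, with 1 term per day over all 9 lists and 6 residual degrees of freedom. A log2 difference is thus relative to the length of the list, and a gene with equal numbers of regions in a longer list is lower. A gene cannot have more regions called than its union regions. Where a large part of them was called on day 4 already, the gene could only come out lower on a later day, whatever happened at its locus. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 16 lists of a comparison, and again with an estimated correlation. Peaks per list and shares were compared by exact permutation tests over all 20 arrangements of 3 against 3 lists. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

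The gene fit was tested on simulated data for day 21 against day 8, with 7831 genes of which 200 were changed 2-fold, in 5 draws. It did not recover them cleanly. With every region of a changed gene called less often, it recovered 32 to 50 of the 200 and called 57 to 67 unchanged genes. With whole regions closed in all lists of a day, a second kind of simulation added after the result of the first kind was seen, it recovered 110 to 121 and called 63 to 78 unchanged genes. No recovered gene had the wrong direction. Because lists of a day are so alike, many genes have the same count in all 3 lists, and their estimated spread is too small.

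In all, 5 estimates of the spread were tried, after this test and the counts from the real lists had been seen. The fit fixed before the data were examined was kept as the one reported. A floor at the spread of 1 region called with a probability of 0.5 in each list recovered 11 to 24 and 62 to 72 of the 200 and called 0 to 1 and 0 to 2 unchanged genes in the respective simulations. The other estimates, without robust fitting, with a floor at the prior spread, and with both, called 12 to 78 unchanged genes. Single calls between days 8 and 21 are therefore not firm, and the floor's values stand beside them. The calls against day 4 come from the same fit, which was not tested on simulated data for those comparisons. Small p-values there can also rest on a spread that is too small.

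The genes named were fixed before the data were examined: 30 core genes of T cell memory, effector function, inhibition and activation in every comparison, and the 5 genes with the largest positive and the 5 with the largest negative difference among those past the threshold. Of the core genes, 1 is not reported here by name but is part of all counts. For core genes, the gained and the lost region called by the most bases are given with coordinates, at most 1 of each per comparison, and a window 22 to 25 kb from Pdcd1 was searched. Without strand, that window was placed beyond the gene's end coordinate. Members of lists named as examples beside them were chosen after their values were seen.

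Alternatives were a −log10 q of at least 5, lists reduced to the 19499 strongest peaks (the length of the shortest list), other rules for calling, gaining and placing a region, no division by list totals, a pseudocount of 1, other minimums of regions, a replicate term, and each list left out in turn. The spread estimates and a fit without the day 4 libraries were added after the data were seen.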

Results

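Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse CD8 T cells taken from lymph nodes that drain a tumor. The cells were P14 cells, which carry a transgenic T cell receptor for a peptide of the glycoprotein of lymphocytic choriomeningitis virus (LCMV), and their hosts bore a B16 melanoma made to express that glycoprotein. Per the labels, 500000 naive P14 cells were transferred 8 days after the tumor cells, and activated donor cells were sorted 4, 8 or 21 days after the transfer. The 9 libraries, 3 per day, were each made from 50000 cells, and each came with 1 list of peaks on mm10.

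On chromosomes 1 to 19 and X, the day 4 lists held 20534 ± 1496 peaks (mean ± SD, 3 lists), the day 8 lists 48811 ± 1776 and the day 21 lists 48420 ± 2832. The lists give no read totals. The smallest local background behind the peaks, which scales with the reads of a library, was 2.89 ± 0.424 tags on day 4, 2.38 ± 0.246 on day 8 and 2.60 ± 0.414 on day 21. At the 15109 regions called in all 9 lists, the median summit pileup was 10.98 ± 0.298 times that background on day 4, 27.7 ± 0.977 times on day 8 and 26.1 ± 1.46 times on day 21.

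The 3 lists of a day were closer to each other than to lists of other days, with a mean Jaccard index of 0.774 within days and 0.520 between days (exact permutation test over 280 partitions, one-sided p = 0.00357, the smallest it can give). Between days 8 and 21 alone the mean was 0.752, against 0.785 and 0.787 within these days, while pairs of day 4 with other days ran from 0.356 to 0.457. Summit pileups of same-day lists differed by less than sampling noise, with a chi-square per region of 0.417 to 0.444 over the 9 same-day pairs, against 0.965 to 1.204 over the 27 pairs of different days. No pair was a copy, since the highest Jaccard index within a day was 0.794. Whether the 3 lists of a day come from separate animals is left open, so each SD below is over lists, and each p-value describes these lists, not animals.

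**Figure D1:**
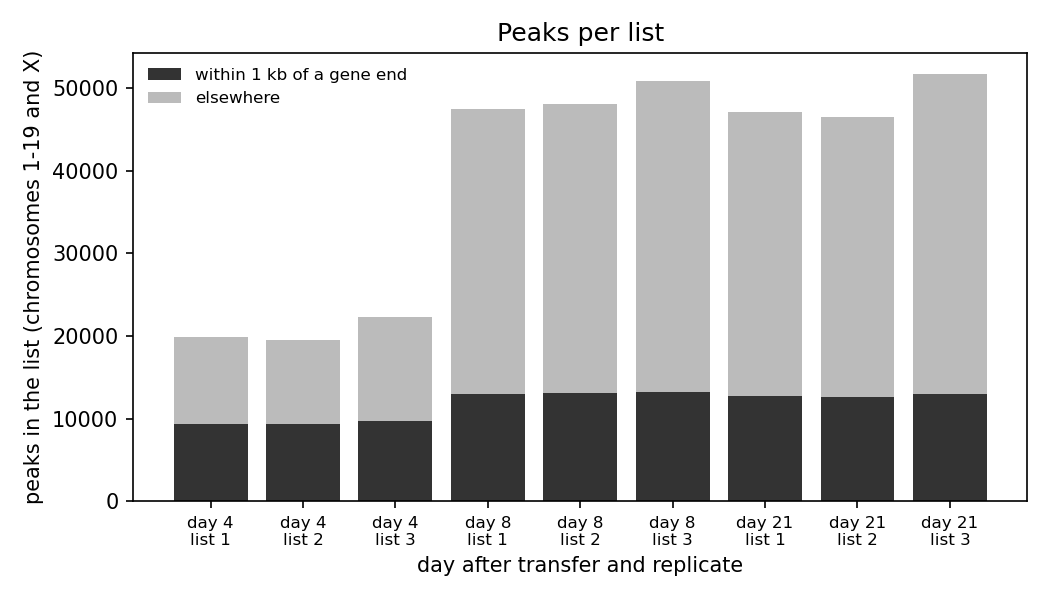
Peaks on chromosomes 1 to 19 and X in each of the 9 lists, split into peaks within 1 kb of either end of an annotated protein-coding gene (dark) and all others (light). The 3 day 4 lists hold 19499 to 22250 peaks, the day 8 lists 47513 to 50835 and the day 21 lists 46492 to 51671.

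Day 8 was compared with day 4 to see how accessible chromatin changed as transferred cells passed from early activation in the draining node, in a study whose stated interest is the basis of memory-like CD8 T cells there. The largest positive differences reported for core genes were at 3 loci with almost no called region on day 4. Tbx21, which encodes the effector transcription factor T-bet, went from 0 regions in each day 4 list to 4.67 ± 1.15 of its 6 (log2 difference relative to all called regions 2.04 ± 0.25 SE, adjusted p = 0.000218, limma). Havcr2, the gene of the inhibitory receptor TIM-3, went from 0 to 4 in every list (1.87 ± 0.16, adjusted p = 4.38e-05), and Lag3, another inhibitory receptor gene, from 0.333 ± 0.577 to 5.67 ± 1.15 (1.78 ± 0.38, adjusted p = 0.00378). Tcf7, which encodes TCF-1, the factor of memory-like and stem-like CD8 T cells, already had 6.67 ± 0.577 regions on day 4 and had 11.7 ± 0.577 on day 8, a smaller gain than that of the whole list (log2 difference −0.54 ± 0.09, adjusted p = 0.00108). It would have come out lower even with all 15 of its union regions called on day 8.

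The effector list had 10 of its 24 tested genes higher on day 8 relative to the list totals and 3 lower, the same numbers when adjusted over the list alone, and the list as a whole did not pass (camera, adjusted p = 0.0878). Besides Tbx21, the higher members included Zeb2, a transcription factor of terminal effector cells (0.95), Klrg1, a receptor of terminal effectors (0.57), and Ifng, the gene of interferon-γ, which went from 6 ± 1 regions to 19 ± 1 (0.29, adjusted p = 0.0287). Prf1, the gene of the pore-forming protein perforin, was lower relative to the total (−0.70) with 2 regions on day 4 and 3.33 ± 0.577 on day 8. With all 4 of its union regions called on day 8 it would still have been lower. Gzmb, Prdm1, Cx3cr1 and Ccl5 did not pass, with log2 differences of 0.32, −0.15, 0.13 and −0.18. The single region of Gzma was too few to test and was called in 2 of the 3 day 4 lists and in all later lists.

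Of the 30 memory and stemness genes, 4 were higher and 9 lower relative to the totals, or 4 and 10 adjusted over the list alone, and the list did not pass (adjusted p = 0.842). The higher genes were Foxo1, a factor that maintains memory T cells (0.60, from 5 ± 1 to 20 ± 3 regions), Bcl6 (0.83), Tcf12 (0.84) and Dapl1 (1.03). None of the 4 passed on the 19499 strongest peaks of each list, where Foxo1 had 0.42 (adjusted p = 0.181), Dapl1 0.17 (0.842), and Bcl6 and Tcf12 the opposite sign, −0.86 (0.335) and −0.66 (0.192). Il7r, which encodes the interleukin-7 receptor chain, was lower relative to the totals (−0.45, from 2 to 4 regions). All 4 of its union regions were called on day 8, so it could not have come out higher. Lef1, Ccr7, Bach2, Id3, Slamf6 and Cxcr3 did not pass, and their log2 differences were −0.23, −0.13, −0.01, −0.45, −0.10 and −0.40.

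Of the 27 inhibitory receptor and exhaustion genes, 7 were higher and 9 lower, or 8 and 11 adjusted over the list alone (list adjusted p = 0.960). Pdcd1, the gene of PD-1, had 3.33 ± 0.577 regions on day 4 and 5.33 ± 0.577 on day 8 (−0.69 ± 0.16, adjusted p = 0.00698). With all 8 of its union regions called on day 8 it would still have been lower relative to the totals. Tigit was lower as well (−0.34), while Tox, Ctla4 and Entpd1 did not pass (0.13, −0.14 and −0.27). Early activation genes were higher for 2 and lower for 7 of 28, or 1 and 7 adjusted over the list alone (list adjusted p = 0.552). Icos, a costimulatory receptor, was higher (0.91), and Nr4a1 and Junb, which respond to receptor signals, were lower (−1.11 and −1.06). Il2ra, Irf4, Batf and Myc did not pass (0.29, 0.01, −0.02 and 0.03).

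Other lists of T cell genes did not pass as lists. Tissue residency genes were higher for 3 and lower for 6 of 15, the same when adjusted over the list alone (list adjusted p = 0.552), with the retention receptor gene Cd69 lower (−0.73). Interferon response genes were higher for 2 and lower for 8 of 16, also the same over the list alone (list adjusted p = 0.552), and Ifi44, called in no list of either day, is among the lower only through the division by list totals. Cell division genes were higher for 1 and lower for 2 of 12 (list adjusted p = 0.842), and genes of CD8 T cell identity were higher for 6 and lower for 5 of 19 (list adjusted p = 0.807). Themis, which acts in T cell development, went from 1.67 ± 0.577 to 12.3 ± 0.577 regions (1.30), but had −0.33 on the 19499 strongest peaks (adjusted p = 0.501). Cd8a went from 4 to 5.67 ± 0.577 (−0.85). These last counts were also the same over each list alone.

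Constitutive genes were lower as a list (adjusted p = 0.0197), but not with an estimated correlation (adjusted p = 0.162), on the 19499 strongest peaks (0.529), at the stricter q (0.0777), with at least 6 regions (0.367) or within 50 kb (0.0594). In the list 11 of 16 were lower and 1 higher, also when adjusted over the list alone. Its 30 genes held 85 union regions, of which a day 4 list called 45 ± 3.61. Even with all 85 called, they could not have risen as much as all called regions, from 19043 to 46908 per list. In total the list was thus bound to be lower relative to the list totals. Eef1a1, which encodes a translation elongation factor, had 2 regions in each list of both days (−1.30), and Snrpd3, a splicing gene, had 3 (−1.30), so these genes did not lose regions.

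Of the lists for other cell types, only the stromal and endothelial one passed. It was higher (camera, adjusted p = 0.0197, and adjusted p = 0.162 with an estimated correlation), with 4 of 8 genes higher and 0 lower, the same over the list alone. These were Kdr and Cdh5, genes of endothelial cells (2.06 and 1.96), Pdgfra, a fibroblast receptor gene (1.84), all with 0 regions on day 4, and Vwf (0.62). The list also did not pass on the 19499 strongest peaks (adjusted p = 0.983), without division by totals (0.371), at the stricter q (0.0957), with at least 6 regions (0.220), within 50 kb (0.0786) or without day 4 list 2 (0.0621). B cell genes were higher for 5 and lower for 1 of 10 (list adjusted p = 0.126), among them the B cell factors Ebf1 (1.87) and Pax5 (1.61). Melanoma genes were higher for 2 and lower for 2 of 6 (list adjusted p = 0.842), NK cell genes for 3 and 3 of 9 (0.842), CD4 and regulatory T cell genes for 2 and 4 of 11 (0.933), myeloid and dendritic cell genes for 0 and 1 of 8 (0.960), and erythroid and platelet genes for 0 and 0 of 2 (0.960). Adjusted over the list alone, these counts did not differ.

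Over all 7831 genes with at least 3 regions, 1287 were higher and 2155 lower on day 8 relative to the list totals (limma, Benjamini-Hochberg adjusted). Of the 2155, 1988 had more called regions on day 8 than on day 4, 149 had as many and 18 had fewer. The largest positive differences were at Rfx8 and Rapgef5 (both 2.89, from 0 to 8.67 ± 0.577 regions), Pald1 (2.78, from 0 to 8), Rhcg (2.72) and Ncald (2.65). The largest negative ones were at Zfp993 (−2.60, from 1 ± 1 to 0), Zfp992 (−2.52), Fpr-rs4 (−2.08), Gm38510 (−1.96) and 4931408C20Rik (−1.87). How reads with several matching places were treated is not given in the sources used here, so values of genes with similar copies, such as these zinc-finger genes, are uncertain. Where a locus had no region on day 4, its log2 difference depends on the pseudocount of 0.5.

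Region by region, 16206 of the 62963 union regions were called in all 3 day 8 lists and no day 4 list, and 6 the other way round. With every list reduced to its 19499 strongest peaks these numbers were 861 and 397. Of the gained regions 13.1% lay within 1 kb of a gene end, against 53.0% of the 15109 regions called in all 9 lists. A day 4 list held 9478 ± 219 peaks near gene ends and 11056 ± 1277 others, and a day 8 list 13100 ± 146 and 35711 ± 1643, so the share near gene ends was 46.3% ± 2.22 on day 4 and 26.9% ± 0.697 on day 8 (exact permutation test, two-sided p = 0.1). Most of that difference goes with list length, since among the 19499 strongest peaks of each list it was −3.08 percentage points in place of −19.4 (exact permutation test, two-sided p = 0.1). The number of peaks per list was 2.38 times higher on day 8 (exact permutation test, two-sided p = 0.1). With 3 lists against 3, no smaller p than 0.1 is possible in these tests.

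Of the 30 core genes, 28 gained at least 1 region and 0 lost one. The widest-called gained regions overlapping gene bodies were at chr11:97114581-97115561 in Tbx21, chr11:46466675-46467351 in Havcr2, chr3:131139352-131140097 in Lef1, chr4:32405545-32406330 in Bach2, chrX:101733772-101734446 in Cxcr3 and chr10:61301096-61301372 in Prf1. Further ones were at chr10:44443669-44444213 in Prdm1, chr9:120068048-120068590 in Cx3cr1, chr11:83530395-83530776 in Ccl5, chr4:6817179-6817725 in Tox, chr19:40687232-40687839 in Entpd1 and chr2:11692895-11693513 in Il2ra. Those of Tbx21, Cxcr3, Cx3cr1, Ccl5 and Il2ra reach past the gene's end coordinate. Outside gene bodies, they were at chr11:52309474-52309813, 26.1 kb from Tcf7, chr10:118470359-118471021, 24.5 kb from Ifng, chr6:124901817-124902324, 2.04 kb from Lag3, chr1:94053558-94054047, 1.01 kb from Pdcd1, chr2:44960191-44960962, 22.6 kb from Zeb2, and chr6:122293810-122294242, 10.98 kb from Klrg1. Near other memory genes, they were at chr11:99125089-99125748 for Ccr7, chr15:9535232-9535620 for Il7r, chr4:136123034-136123394 for Id3 and chr1:171915665-171916454 for Slamf6. The remaining ones were at chr14:56275766-56276502 for Gzmb, chr16:43708310-43708776 for Tigit, chr1:60875145-60875660 for Ctla4, chr13:30747520-30748042 for Irf4 and chr12:85712458-85713019 for Batf. Myc and Gzma gained none.

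The direction of these gene calls depends on how list length is treated. Without division by the list totals, all 29 tested core genes were higher on day 8, Tcf7 and Pdcd1 included (0.77 and 0.61), 6650 genes were higher and 0 lower, and the median log2 difference of all genes moved from −0.14 to 1.17. With each list reduced to its 19499 strongest peaks, 370 genes were higher, all with more regions on day 8. Of the 2598 lower, 2319 had equal numbers of regions on both days and passed only through the division, so that count is not read as a change. There Tbx21 had 1 region in every day 8 list and 0 on day 4, while Havcr2 (1.21, adjusted p = 0.278), Lag3 (−0.62, adjusted p = 0.551), Tcf7 (−0.23, adjusted p = 0.0652) and Pdcd1 (−0.09, adjusted p = 0.686) stopped passing. So did Klrg1 (0.16, adjusted p = 0.703), Ifng (0.06, 0.786), Icos (0.19, 0.406), Junb (−0.41, 0.620), Cd69 (−0.52, 0.188), Cd8a (−0.09, 0.553), Snrpd3 (−0.25, 0.190), Vwf (0.40, 0.312), Ebf1 (0.97, 0.259) and Pax5 (−0.09, 0.905). Of the genes with the largest differences, Rapgef5 (0.617), Pald1 (0.370), Rhcg (0.476), Zfp993 (0.0728), Zfp992 (0.342) and Fpr-rs4 (0.305) stopped passing too. Kdr, Cdh5, Pdgfra and Ncald were then called in no list of either day. A pseudocount of 1 gave 785 higher and 3313 lower (19.2% higher, against 37.4%), and a minimum of 6 regions gave 673 and 617 (52.2%). With a floor at the spread of 1 call, Klrg1 (adjusted p = 0.0698), Il7r, Tigit and Vwf (0.0504 each) and Ifi44 (0.135) stopped passing. Under that floor Tbx21, Havcr2 and Lag3 still passed, with weaker support (limma, adjusted p = 0.00816, 0.0119 and 0.00591).

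**Figure D2:**
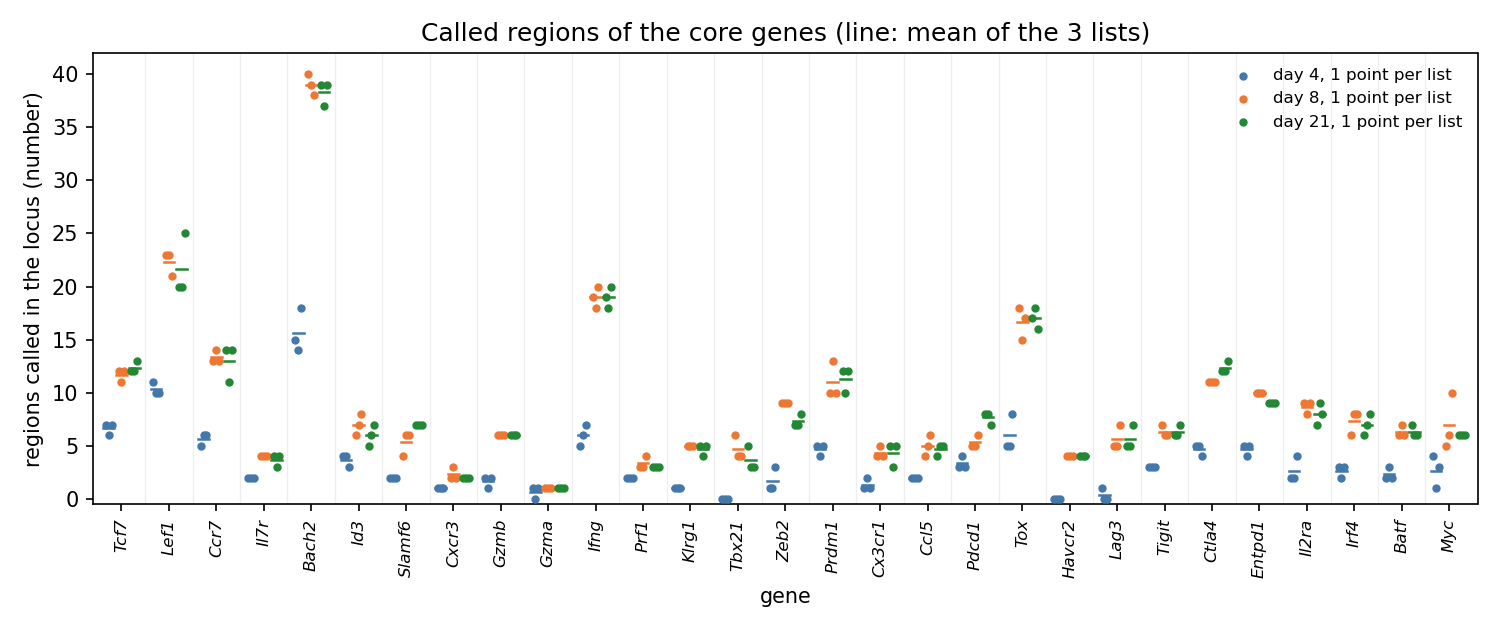
Number of regions called in the locus of each core gene reported here (vertical axis), 1 point per list, with a line at the mean of the 3 lists of day 4 (blue), day 8 (orange) and day 21 (green). Havcr2 and Tbx21 have 0 regions in all day 4 lists, while Tcf7 has 6.67 on average on day 4, 11.7 on day 8 and 12.3 on day 21.

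Day 21 was compared with day 8 to see what differed between an intermediate and a late stage in the node. Numbers of regions at the core genes differed little between these days, and none of the 29 tested genes passed on the full lists. Tcf7 had 11.7 ± 0.577 regions on day 8 and 12.3 ± 0.577 on day 21 (log2 difference 0.09 ± 0.09, adjusted p = 0.866), Havcr2 had 4 in every list of both days, and Ifng had 19 ± 1 on both. The largest difference among them was at Pdcd1, with 5.33 ± 0.577 regions on day 8 and 7.67 ± 0.577 of its 8 on day 21 (0.50 ± 0.16, adjusted p = 0.264, limma). Slamf6, whose product marks progenitor-like exhausted cells, had 5.33 ± 1.15 and 7 regions (0.40, adjusted p = 0.362), and Tbx21 had 4.67 ± 1.15 and 3.67 ± 1.15 (−0.31, adjusted p = 0.775). On the strongest peaks of each list, Tbx21 alone among the core genes passed, lower on day 21 (−1.58, adjusted p = 6.93e-09, limma). That call rests on 1 region, called there in every day 8 list and no day 21 list, with no spread between lists of a day.

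In the gene body of Pdcd1, the region chr1:94042182-94042822 was called in 3 of 3 day 21 lists and in none of day 8 or day 4. A region 94.5 kb beyond the gene's end coordinate, chr1:94147085-94147790, was called in 0, 1 and 3 lists of days 4, 8 and 21. No region lay in a window fixed in advance at 22 to 25 kb beyond that end. The nearest, chr1:94078941-94079485 at 26.4 kb, was called in all 9 lists. Among the other core genes, Ctla4 gained chr1:60910868-60911105 in its body, Il2ra lost chr2:11655408-11655684 in its body, and Zeb2 lost chr2:45138997-45139220, which is 21.6 kb past its end coordinate.

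**Figure D3:**
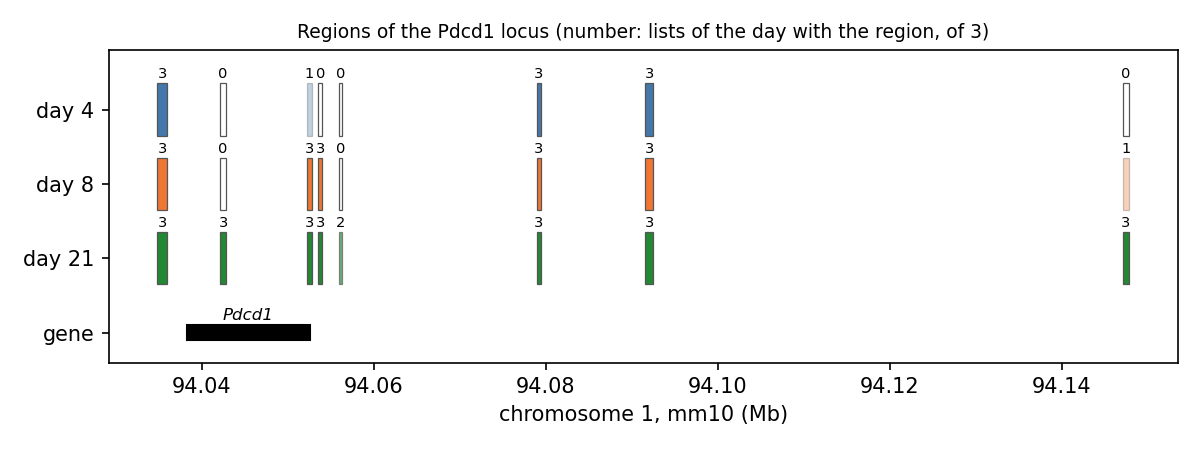
The 8 called regions of the Pdcd1 locus on chromosome 1 (mm10, horizontal axis in Mb), drawn to scale for each day, with the gene as a black bar. The number over each box is how many of the 3 lists of that day had the region, and the left one of the boxes that overlap the gene body reads 0, 0 and 3 on days 4, 8 and 21.

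Over all 7831 genes, 0 were higher and 2 lower on day 21 (limma), and at an unadjusted p under 0.05 431 were higher and 444 lower. The counts depend on the setting, with 85 higher and 117 lower without division by totals, 63 and 86 on the 19499 strongest peaks, 12 and 14 at the stricter q, and 85 and 175 with no minimum of regions. Foxf2, a forkhead transcription factor gene of mesenchymal tissue at chr13:31625816-31631406, had 3.33 ± 0.577 regions on day 8 and 0 in each day 21 list (−2.92 ± 0.30, adjusted p = 0.0133). Fam168a, at chr7:100706628-100841646, had 5 in each day 8 list and 2 in each day 21 list (−1.13 ± 0.13, adjusted p = 0.0197). On the strongest peaks neither passed (adjusted p = 1.00 each). Both also stopped passing (adjusted p = 0.141 for each) when a gene's spread was not allowed to fall below that of 1 region called in some lists and not others. In simulated lists with 200 changed genes, the test as used also called 57 to 78 unchanged genes. No lists without changed genes were simulated, so how many false calls to expect here is not known. Neither call is firm.

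Tissue residency genes were higher on day 21 as a list (camera, adjusted p = 0.0332, and adjusted p = 0.560 with an estimated correlation), with 0 of 15 members past the threshold, also over the list alone. Ahr, a ligand-activated transcription factor gene, had 2.33 ± 0.577 and 4.67 ± 1.53 regions (0.85, adjusted p = 0.177), and Cd69 had 11.7 ± 0.577 and 14 ± 1 (0.26, adjusted p = 0.349). Itgae, the gene of the integrin CD103, had a negative difference (−0.35, adjusted p = 0.234). The list did not pass on the 19499 strongest peaks (adjusted p = 0.487), with at least 6 regions per gene (0.145) or with boundaries within 50 kb (0.156). Nor did it pass without day 8 list 2 (0.114), day 21 list 1 (0.252) or day 21 list 3 (0.0591).

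No other list passed. The effector list was nearest (lower, adjusted p = 0.327), with Itgax, an integrin gene, lower over the list alone (−1.21, 3 regions to 1). The melanoma list had an adjusted p of 0.447 and the NK cell list 0.687, each with 1 gene higher over the list alone, Dct and Eomes (1.56 and 0.41). The interferon list had 0.952, with Ifi44 higher over the list alone (2.37), and the stromal and endothelial list 0.952, with Kdr lower over the list alone (−0.70). Early activation, constitutive, and CD4 and regulatory T cell genes each had 0.705. Memory and stemness, inhibitory receptor, cell division, CD8 identity, B cell, myeloid, and erythroid genes each had 0.952, and in these 10 lists no gene passed over the list alone.

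By region, 640 were called in all 3 day 21 lists and no day 8 list, and 688 the other way round. With 1 list left out these ranged from 865 to 1336 and from 912 to 1425, and with 2 of 3 lists sufficient they were 2171 and 2297. Both settings loosen the rule, so neither could give fewer regions than the main one. Of the gained regions 42 (6.56%) lay within 1 kb of a gene end and of the lost ones 104 (15.1%; Fisher's exact test, two-sided p = 6.69e-07, over regions, which are not replicates). None of either set was among the 19499 strongest peaks of all 3 lists. Peaks per list differed by −391 and the share near gene ends by −0.339 percentage points, less than the spread between lists (exact permutation tests, two-sided p = 0.7 and p = 0.5, smallest possible p 0.1). Among the 19499 strongest peaks of each list the share was 44.2% ± 0.140 on day 8 and 42.8% ± 0.183 on day 21, a difference of −1.42 percentage points and beyond that spread (exact permutation test, two-sided p = 0.1).

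Day 21 was compared with day 4 to give the change over the whole course. Havcr2 went from 0 to 4 regions in every list (log2 difference 1.88 ± 0.16, adjusted p = 4.82e-05, limma), Lag3 from 0.333 ± 0.577 to 5.67 ± 1.15 (1.79 ± 0.38, adjusted p = 0.00385) and Tbx21 from 0 to 3.67 ± 1.15 (1.73 ± 0.25, adjusted p = 0.000536). Zeb2 (0.68), Klrg1 (0.49) and Ifng (0.31) were higher too. Relative to the totals Tcf7 was lower (−0.45 ± 0.09, adjusted p = 0.00316), with 6.67 ± 0.577 regions on day 4 and 12.3 ± 0.577 on day 21. So were Il7r (−0.56), Id3, an inhibitor of E proteins in memory cells (−0.65), Cxcr3, a chemokine receptor gene (−0.55), Prf1 (−0.80) and Entpd1, which encodes the ectoenzyme CD39 (−0.41). Tcf7 and each of these lower genes would have come out lower even with all of their union regions called on day 21.

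The other core genes did not pass. Pdcd1 went from 3.33 ± 0.577 to 7.67 ± 0.577 regions (−0.19, adjusted p = 0.356). Lef1, Ccr7, Bach2 and Slamf6 had log2 differences of −0.26, −0.16, −0.02 and 0.29, and Gzmb, Prdm1, Cx3cr1 and Ccl5 of 0.33, −0.09, 0.12 and −0.25. Those of Tox, Tigit and Ctla4 were 0.17, −0.33 and 0.03, and those of Il2ra, Irf4, Batf and Myc 0.19, −0.04, −0.00 and −0.11.

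Among the lists, constitutive genes were lower (camera, adjusted p = 0.00400, and adjusted p = 0.124 with an estimated correlation, 0.464 on the 19499 strongest peaks and 0.296 with at least 6 regions), with 12 of 16 lower and 0 higher. Gapdh, a glycolytic enzyme gene, had 1.67 ± 0.577 regions on day 4 and 2 on day 21 (−1.04). Here too, so many of the constitutive list's union regions were called on day 4 that in total it could not rise as much as all called regions. Stromal and endothelial genes were higher (adjusted p = 0.0135, and adjusted p = 0.140 with an estimated correlation, 0.821 on the 19499 strongest peaks, 0.373 without division by totals, 0.0889 at the stricter q and 0.296 with at least 6 regions), with 4 of 8 higher and 0 lower: Cdh5 (2.25), Pdgfra (1.76), Kdr (1.36) and Vwf (0.64). B cell genes were higher for 4 and lower for 1 of 10 (list adjusted p = 0.0747), with H2-Aa, an MHC class II gene, going from 0 to 4 regions (1.88). These counts were the same over each list alone.

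Effector genes were higher for 8 and lower for 3 of 24 (list adjusted p = 0.374), and memory and stemness genes for 4 and 8 of 30 (0.901). Early activation genes were higher for 1 and lower for 6 of 28 (0.641), tissue residency genes for 2 and 5 of 15 (1.00), and cell division genes for 1 and 6 of 12 (0.752). Melanoma genes were higher for 2 and lower for 1 of 6 (0.439), with Gpnmb, also a gene of macrophages, going from 0 to 6 ± 1 regions (2.40). NK cell genes were higher for 3 and lower for 2 of 9 (0.6003), CD4 and regulatory T cell genes for 2 and 6 of 11 (0.752), myeloid and dendritic cell genes for 1 and 2 of 8 (1.00), and erythroid and platelet genes for 0 and 0 of 2 (1.00). Adjusted over the list alone, the counts in these 10 lists were the same. Inhibitory receptor genes were higher for 6 and lower for 8 of 27, or 6 and 9 over the list alone (1.00), interferon genes for 1 and 6 of 16, or 2 and 7 (0.641), and CD8 identity genes for 4 and 5 of 19, or 6 and 5 (0.641).

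Over all genes 1274 were higher and 2137 lower, and of the 2137, 1963 had more called regions on day 21 than on day 4, 161 as many and 13 fewer. The largest positive differences were at Rfx8 (3.05), Pald1 (2.84), Rapgef5 (2.79), Vps54 (2.68) and Gipc2 (2.68), each from 0 regions. The largest negative ones were at Zfp992 (−2.75), Gm8127 (−2.35), Zfp993 (−2.06), Zfp985 (−1.82) and Zfp982 (−1.66). The zinc-finger genes among them lie close together on chromosome 4, and whether they share reads was not tested. By region, 15913 were gained and 5 lost. The gained region called by the most bases was the one given above for each core gene named there, and Myc gained chr15:62031895-62032507. With lists of 19499 peaks these were 891 and 372. The share near gene ends was 26.5% ± 1.12 on day 21 against 46.3% ± 2.22 (−4.50 percentage points with lists of 19499 peaks, in place of −19.7), and peaks per list were 2.36 times higher (exact permutation tests, two-sided p = 0.1 each, the smallest possible).

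Here too the gene calls depend on list length. Without division by the totals 6516 genes were higher and 0 lower (median log2 difference of all genes 1.14 in place of −0.15), Tcf7 included (0.84). On the 19499 strongest peaks 355 were higher, all with more regions on day 21, and of the 2600 lower 2348 had equal numbers of regions on both days. There Tbx21 was called in no list of either day, and Havcr2 (1.21, adjusted p = 0.283) and Lag3 (0.69, adjusted p = 0.499) stopped passing. So did Klrg1 (0.16, adjusted p = 0.708), Ifng (0.30, 0.191), Il7r (−1.11, 0.172), Id3 (−0.09, 0.699), Entpd1 (0.01, 0.945), Vwf (0.40, 0.315) and Gpnmb (−0.09, 0.872). Of the genes with the largest differences, Pald1 (0.190), Rapgef5 (0.264), Vps54 (0.137), Gipc2 (0.872), Zfp992 (0.345), Gm8127 (0.315) and Zfp993 (0.0729) stopped passing too, and Kdr, Cdh5 and Pdgfra were called in no list of either day. With a floor at the spread of 1 call, Klrg1 and Cxcr3 stopped passing (adjusted p = 0.113 each). Under that floor Tbx21, Havcr2 and Lag3 still passed, with weaker support (limma, adjusted p = 0.0177, 0.0126 and 0.00635). A pseudocount of 1 gave 723 and 3313 (17.9% higher, against 37.3%), no minimum of regions 1648 and 7643 (17.7%), and a minimum of 6 regions 704 and 550 (56.1%).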

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

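No test was run in this part. Chromosome Y was outside all comparisons, and the lists held more peaks there than the 3 that a count of 0 would allow. The day 4 lists had 19, 19 and 24 peaks on it, the day 8 lists 21, 20 and 21, and the day 21 lists 22, 22 and 26.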

How the results depend on the processing

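The 4 other spread estimates and the fits without the day 4 libraries were chosen after seeing the data. The 4 planned motif alternatives were not run, for want of a genome, and the erythroid list gave no value at a minimum of 6 regions. Of 2299 values of named genes under alternatives, 126 stopped passing, 63 began to pass and 43 reversed. The other 2067 stayed on their side of the threshold and were not counted as reversed. For the gene lists, 25 stopped passing, 15 began to pass, 4 reversed and 833 of 877 were left. A reversal was counted only where the main or the alternative fit passed, so the 2067 and the 833 can include changes of sign where neither did. Examples on the strongest peaks, for day 8 against day 4, were Id3 (0.03 in place of −0.45) and Cx3cr1 (−0.33 in place of 0.13). Reversals without division by list totals follow from that setting, which adds the same amount to every gene. Where no reason is given for a change below, the cause was not tested. A region without a call is one below the threshold of its list, not one shown to be closed, so all counts of regions depend on the depth and enrichment of a library.

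At a −log10 q of at least 5, the difference in peaks between days 21 and 8 was 345 in place of −391 (exact permutation test, two-sided p = 0.9). With 1 list left out it ranged from −2017 to 620.7, and the difference in the share near gene ends from −0.742 to 0.306 points. On the 19499 strongest peaks, the share differed by −3.08 points between days 8 and 4 (in place of −19.4), by −1.42 between days 21 and 8 (in place of −0.339) and by −4.50 between days 21 and 4 (in place of −19.7), each with p = 0.1 (exact permutation tests, two-sided), the smallest possible.

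On the 19499 strongest peaks, regions gained and lost were 861 and 397 for day 8 against day 4, 402 and 335 for day 21 against day 8, and 891 and 372 for day 21 against day 4. Judged present among the strongest and absent from full lists, gains were 737, 0 and 732, and losses for day 21 against day 8 were 0. With 2 of 3 lists sufficient, losses were 34 and 33 against day 4, and day 21 against day 8 had 2171 gains and 2297 losses. With 1 list left out, losses ranged from 8 to 21 for day 8 against day 4 and from 7 to 18 for day 21 against day 4. For day 21 against day 8, gains ranged from 865 to 1336 and losses from 912 to 1425. Leaving a list out, or letting 2 of 3 suffice, loosens the rule, so these counts could not fall below those of the main rule.

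Genes for day 8 against day 4 were 6650 higher and 0 lower without division by totals, 370 higher on the strongest peaks, 785 and 3313 with a pseudocount of 1, 7490 lower with no minimum of regions, and 673 and 617 with at least 6. Genes for day 21 against day 4 were 6516 and 0, 355 higher, 723 and 3313, 7643 lower, and 704 and 550 under the same settings. Of the 3442 genes called for day 8 against day 4, 1287 were called the same way and 1352 the opposite way without division by totals. For the 3411 of day 21 against day 4 these were 1274 and 1273. On the strongest peaks most genes called lower had equal numbers of regions on both days (2319 of 2598 for day 8 against day 4, and 2348 of 2600 for day 21 against day 4), as had 419 of 477 and 396 of 440 genes called opposite to the full lists. Such calls follow from the division by totals and a spread near 0, and are not reversals.

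Genes for day 21 against day 8 were 85 higher and 117 lower without division by totals, 63 and 86 on the strongest peaks, 12 and 14 at the stricter q, 85 and 175 with no minimum, 0 lower with at least 6 regions, 2 higher with a pseudocount of 1 and 2 higher with boundaries within 50 kb. They were 5 and 7 without the day 4 libraries, 1 higher without robust fitting, and 0 lower under each floor of the spread (at the prior, at the prior without robust fitting, and of 1 call). With 1 list left out, 0 to 2 were higher and 0 to 8 lower: 0 were lower without day 4 list 1 or any single day 8 list, and 8 without day 21 list 3. Under the floor of 1 call, 924 were higher and 1894 lower for day 8 against day 4, and 867 and 1865 for day 21 against day 4.

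The deviations of same-numbered lists from their day's mean had correlations of −0.0296 to 0.0248, so these values showed no pairing by replicate number. They cannot exclude one, since the origin of the 3 lists of a day is not known. The list numbered 3 held the most peaks on each day (22250, 50835 and 51671 on days 4, 8 and 21). With the replicate block, 0 genes were lower for day 21 against day 8, 1174 were higher and 1980 lower for day 8 against day 4, and 1127 and 1961 for day 21 against day 4. Lists past the threshold with the block numbered 2, 1 and 2, as without it. The block left the differences in peaks at 28277, −391 and 27885 and in the share near gene ends at −19.4, −0.339 and −19.7 points (exact sign flips, two-sided p = 0.25 each, the smallest possible, but 0.75 for the −391).

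Gene lists past the threshold for day 8 against day 4 were 1 without division by totals, 0 on the strongest peaks, 0 at the stricter q, 5 with no minimum, 0 with at least 6 regions, 1 with boundaries within 50 kb and 0 with an estimated correlation. For day 21 against day 4 they were 1, 0, 1, 10, 0, 4 and 0. For day 21 against day 8 they were 0 on the strongest peaks, with at least 6 regions, within 50 kb and with an estimated correlation. With 1 list left out they ranged from 1 to 2 for day 8 against day 4 and from 0 to 1 for day 21 against day 8. On the strongest peaks the stromal and endothelial list stopped passing (limma's camera, adjusted p = 0.983 and 0.821 on days 8 and 21 against day 4). Its direction by camera, which compares moderated t values, was then lower, while its mean log2 differences of 0.22 and 0.13 lay above the median of all genes. With no minimum, for day 21 against day 4, the inhibitory receptor list turned higher (mean 0.0559) and the myeloid list higher (mean −0.0897), each relative to a lower median of all genes.

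Without division by totals, log2 differences for day 8 against day 4 reversed at Tcf7 (0.77), Lef1 (1.08), Ccr7 (1.17), Il7r (0.85), Bach2 (1.30), Id3 (0.85), Slamf6 (1.202), Cxcr3 (0.90), Prf1 (0.61), Prdm1 (1.15), Ccl5 (1.12), Pdcd1 (0.61), Tigit (0.96), Ctla4 (1.16), Entpd1 (1.03) and Batf (1.29). For day 21 against day 4 they reversed at Tcf7 (0.84), Lef1 (1.03), Ccr7 (1.13), Il7r (0.73), Bach2 (1.27), Id3 (0.64), Cxcr3 (0.74), Prf1 (0.49), Prdm1 (1.197), Ccl5 (1.04), Pdcd1 (1.10), Tigit (0.96), Entpd1 (0.88), Irf4 (1.25), Batf (1.29) and Myc (1.18). On the strongest peaks, reversals were at Lag3 (−0.62), Irf4 (−0.90) and Ncald (−0.0882) for day 8 against day 4. For day 21 against day 4 they were at Tbx21 (−0.0878), Entpd1 (0.00874) and Gipc2 (−0.0878), and for day 21 against day 8 at Foxf2 and Fam168a (both 0.000426). Ncald, Tbx21, Gipc2, Foxf2 and Fam168a are among these only through the division by totals, which gives such values to genes with equal numbers of regions on both days. At the stricter q, reversals were at Slamf6 (0.57) for day 8 against day 4 and at Il7r (0.13) and Myc (1.09) for day 21 against day 4.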

Other observations

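Every test in this part was chosen after the result was seen, apart from the comparison of regions near gene ends and elsewhere at equal day 8 strength and width, whose averaging over 50 strata was set after the values at equal strength alone were seen. Some regions that were strong on day 8 had no peak at all on day 4. Of 16485 regions among the 19499 strongest peaks of all 3 day 8 lists, 737 were in no day 4 list of any strength, and 15.2% of those lay within 1 kb of a gene end, against 49.0% of the 16485. On day 21, 732 of 16577 such regions were in no day 4 list, and 9.97% lay near a gene end.

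The share of regions gained from day 4 to day 8 was 25.7% over all regions, and over the 16 gene lists it ran from 16.5% (14 of 85, constitutive genes) to 37.5% (24 of 64, B cell genes). Whether the lists differ in this share was not tested.

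The day 4 lists held fewer peaks than those of day 8. Fewer reads on day 4 are argued against by the genome background, which was 1.22 times that of day 8, and lower enrichment over background was there, with a median ratio of day 4 to day 8 of 0.396 at regions called in all lists. A uniform loss of enrichment as the whole cause was tested only through gene ends, and a loss that was uneven in another way would not show there. In the calls on day 4 at equal day 8 strength and width, regions near gene ends and elsewhere differed by −0.817 percentage points (SD 0.778 over the 3 day 4 lists, 50 strata). Over the 22 strata with 10 to 90% of regions called on day 4 they differed by −1.65 (SD 0.868). Single strata of strength and width ran from −16.0 to 10.8, and at equal strength alone regions near gene ends were called more often by 3.51 points (SD 0.816) over all 10 bins and by 5.33 (SD 1.09) over the 5 bins within these limits, so the result rests partly on matching width. Whether that lower enrichment came from the libraries or from the chromatin of day 4 cells was not tested, so a biological change between the days stays open beside it.

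Lists of 1 day differed by less than sampling noise. The highest Jaccard index within a day, 0.794, argues against copies of 1 list. In the regions with more reads, the highest chi-square per region of same-day pairs was 0.457, below the 1 set in the test for 3 lists from 1 library or pool. That limit cannot tell them from separate libraries, since pairs of days 8 and 21 had 0.905 to 0.957 there, also below 1. Taking a summit lowers the variance by itself, but in the simulated settings to no less than 0.548, above the 0.417 to 0.444 of all same-day pairs. Those settings used assumed peak profiles, and summits of real peaks could vary less than the simulated ones. Separate libraries therefore stay open too, although being alike would not by itself take them below sampling noise. No biological explanation was tested.

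No region gained or lost between days 8 and 21 was among the 19499 strongest peaks of all 3 lists of its day, though summits in the regions with more reads also differed more between these days (chi-square per region 0.905 to 0.957) than within them (0.3797 to 0.402). Over the 15109 regions called in all 9 lists the chi-square was 0.965 to 1.04, partly within and partly above the 0.548 to 0.993 of simulated summits. The 0.905 to 0.957 of the regions with more reads lay within that simulated range. Sampling noise of separate libraries was therefore neither shown nor excluded. Peaks flickering at the calling threshold stay open as the whole cause. The shares near gene ends were unequal, 42 of 640 gained and 104 of 688 lost (Fisher's exact test, two-sided p = 6.69e-07), but regions are not replicates, and the strongest peaks of the lists also differed in that share (44.2% and 42.8%, a comparison added after that p-value was seen), so chance calls could be unequal too. A change of the cells between these days stays open and untested.

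With 3 lists against 3, there are 10 splits, too few for a share under 0.05. In each of the 6 counts below, 1 of the 10 splits, the real one, was as large as the real value. Regions gained and lost were 16212 for day 8 against day 4 (highest other split 63), 1328 for day 21 against day 8 (426) and 15918 for day 21 against day 4 (59). Genes past the threshold were 3442, 2 and 3411, with 0 in every other split. Every other split puts lists of both days in each group. A difference between the days then adds to the spread within groups and leaves few regions or genes to call. The counts of the other splits therefore do not show what chance alone would give.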
